A study of Mus musculus with 6 samples.

How the data were processed

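The series measured transcript levels by RNA sequencing in E14Tg2A cells, an established male mouse embryonic stem cell line. There were 6 libraries, 3 from wild-type (WT) cells and 3 from cells in which Bach1 was disrupted by CRISPR/Cas9 (BACH1-KO). Per the labels' protocols, both genotypes were grown for 2 days in serum medium with 200 units/ml leukemia inhibitory factor (LIF), RNA was taken with Trizol, and libraries were made with an Illumina TruSeq kit. The guide RNAs were delivered on a lentiviral CRISPR plasmid by transfection, cells were selected with puromycin and single-cell clones were sorted. The 3 knockout titles share their opening characters, while the WT titles have either of 2 openings. The closing characters are the same in 2 WT and 1 knockout titles and in 1 WT and 1 knockout title, and 1 knockout title has its own. The labels do not say what these parts stand for, so they leave open whether the knockout libraries come from 1 clone, and whether the closing characters mark a shared day or batch. Because the columns cannot be tied to titles, no comparison within such a batch could be made. The p-values therefore measure the spread between these libraries, which may be technical.

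The deposited table gives FPKM (fragments per kilobase of transcript scaled to the number of mapped fragments) for each gene symbol and library, and the submitters' processing notes name Cufflinks and the mouse genome build mm10. The aligner, the gene annotation and the versions are not given in the sources used here. FPKM divides by library size and transcript length, so a value is a share of the library, and a large rise of some transcripts lowers the share of the others. No read counts were used, so the absolute depth is unknown and no count model was run. Low FPKM values of a gene step by whole fragments, and the commonest ratio of such values between libraries gave relative depths of 1.00, 1.10 and 1.06 for WT and 1.17, 1.17 and 1.01 for BACH1-KO, with the first WT library as the unit. Values under 0.1 FPKM were used for this estimate, and only ratios in a limited range around equal depth were searched. A difference in depth beyond that range could not have been found. An exact 0 in such a table can be a failed estimate, so a gene without a value above 0 is called listed at 0.

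The columns of the table name the genotype but cannot be tied to single sample titles, so each column was used as a replicate of its group with no number or pairing. The table held 18518 gene symbols, each once. Another 23 rows carried a number in place of a symbol, held 0.0987% of the summed FPKM and were left out. The 6 columns were all used.

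Log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) for genes with a mean of at least 1 FPKM over the 6 libraries, 12187 genes in all. The comparison was 3 BACH1-KO against 3 WT libraries, two-sided, with Benjamini-Hochberg adjustment. An adjusted p under 0.05 is called past the threshold, and only such genes are said to have risen or fallen. Every adjusted p of a gene is from this limma test. A log2 fold change is BACH1-KO minus WT on the log2(FPKM + 1) scale, which understates the change of genes with low values. Its standard error (SE) is the moderated one. Levels are means ± SD over 3 libraries.

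Before the data were examined, 26 gene lists were written from general knowledge of mouse embryonic stem cells. They cover general, naive and formative or primed pluripotency, LIF receptor and STAT3 signalling, BACH1 and NRF2 targets, heme and iron handling, the germline, the 2-cell-like state, mesendoderm, endoderm, neuroectoderm, trophoblast, fibroblast feeder cells, glycolysis, hypoxia, oxidative phosphorylation, cholesterol synthesis, the ATF4 and unfolded protein response, p53 targets, the cell cycle, the interferon response, imprinted genes, cytosolic ribosomal proteins, immediate early genes, histone genes and mitochondrially encoded genes. No member of the mitochondrially encoded list had a row in the table, so 25 lists were tested. Lists with at least 5 tested members were tested with camera (limma) with a preset inter-gene correlation of 0.01, which asks whether a list moved relative to the other genes, adjusted over the lists. The same test with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way, were alternatives.

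The text names Bach1; 10 genes fixed beforehand (Pou5f1, Sox2, Nanog, Klf4, Esrrb, Lifr, Il6st, Stat3, Socs3, Hmox1); the 12 genes higher and the 12 lower with the largest log2 fold change among those past the threshold whose libraries separated the groups; and up to 4 members per list with the smallest adjusted p past the threshold. Symbols of the form Gm plus digits or ending in Rik were left out of the naming of top genes, and 103 of those passed the threshold with at least a doubling or halving. Other names were chosen after their values were seen. Further lists were written once the values were known in part (hepatocyte, other liver cell types, hepatoblast and early endoderm, ERK feedback targets, BMP and SMAD targets, Y-linked genes). The levels of the other liver cell types list had not been looked at when it was written. The hepatocyte list was built from genes seen to be high in knockout and from well known liver transcripts.

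Coordinates, GC content and transcript length came from GENCODE M21, on the same build (GRCm38, mm10), matched by symbol. Of the symbols, 94.8% matched, and 95.4% of the tested genes had a GC content and length. Alternatives changed the pseudocount to 0.1, removed the filter or set it to 5 FPKM, applied quantile or median-of-ratios scaling, used a constant or a robust prior variance and left out each library in turn. Alternatives added after the data were seen left out the hepatocyte list or chromosome 6, or tested against a fold change of 1.5 (treat in limma). Other splits of the 6 libraries into 3 and 3 were also fitted.

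The gene and list tests were tested on simulated data drawn from the WT means and the residual spread of the 12187 genes, 3 WT against 3 BACH1-KO, with 50 genes changed at each of 4 sizes. At a log2 change of 0.25 the test recovered 44.0% of changed genes, at 0.5 it recovered 82.0%, at 1 it recovered 98.0% and at 2 it recovered 100%, with 7 false calls. Of 40 simulated lists, the 1 moved by 0.5 passed and 0 of the others did. Genes were simulated independently of each other, most were left unchanged, and all members of the moved list went the same way. The changed genes were taken from those with a WT mean log2(FPKM + 1) above 2. The simulation therefore does not cover correlated genes, genes of low level or data in which most genes differ. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.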

Results

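RNA sequencing was carried out on mouse embryonic stem cells of the E14Tg2A line, 3 WT and 3 BACH1-KO libraries, kept for 2 days in serum medium with LIF, the cytokine that holds these cells in self-renewal through STAT3. BACH1 is a heme-binding transcription factor known for repressing Hmox1 and other genes of the oxidative stress response. The series asks how BACH1 bears on pluripotency and differentiation, and its title names STAT3 and the LIF receptor, so the genes of that pathway are given first after Bach1 itself. Between 16047 and 16159 genes had a value above 0 in the WT libraries, and between 17276 and 17455 in the knockout libraries. The most abundant transcript in each library was Eef1a1, a translation elongation factor, with 1.79% to 1.87% of the summed FPKM in WT and 1.37% to 1.41% in knockout. Pearson's r across tested genes was 0.991 to 0.994 between libraries of a group and 0.929 to 0.935 between groups (genes are not independent replicates). The median coefficient of variation of genes of at least 10 FPKM was 4.19% in WT and 3.18% in knockout. The first principal component held 87.2% of the variance and separated the genotypes, and the second held 4.60%.

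Bach1 transcript was present in the knockout cells and was higher than in WT. The gene lies on chromosome 16 (mm10, 87698945 to 87733346, plus strand), and its level was 7.97, 8.39 and 8.47 FPKM in the WT libraries and 10.5, 10.4 and 10.4 FPKM in the knockout libraries. The log2 fold change was 0.30 (SE 0.05, limma adjusted p = 5.15e-04). An exact two-sided permutation test of these values gave p = 0.1, the smallest that 3 against 3 libraries allow. The level of a transcript does not show whether its coding sequence was edited, so the values neither check nor contradict the genotype labels. The rise was no longer called when tested against a fold change of 1.5.

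Most of the transcriptome differed between the genotypes. Of 12187 tested genes, 9378 (77.0%) passed the threshold, 4542 higher and 4836 lower in knockout, and 9668 (79.3%) had all libraries of one genotype above all of the other, where chance gives 10%. Most changes were small: 956 genes at least doubled and 487 at least halved. Of the doubled genes, 68 belong to a list of hepatocyte transcripts described further on, which made up 0.0148% to 0.0168% of the summed FPKM in WT and 0.228% to 0.232% in knockout. Most of the share in WT came from 2 members expressed in both genotypes, Apoc1 at 72.5 ± 0.247 and Fah at 42.5 ± 2.78 FPKM. The median log2 fold change was -0.01. The balance of directions depended on the processing: with no filter on low values 11655 of 18518 genes passed, 6580 higher and 5075 lower, and with median-of-ratios scaling 50.5% of the 9355 called genes were higher. With a filter at 5 FPKM, 2942 genes were higher and 817 doubled or halved, among fewer genes tested. Tested against a fold change of 1.5, 2319 genes passed, 1325 higher and 994 lower, and 17 named genes, among them Bach1, Pou5f1, Sox2, Nanog and Il6st, did not.

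Lifr, Il6st, Stat3 and Socs3, genes of the LIF pathway, were lower in the knockout cells. Lifr, the LIF-binding receptor subunit (chromosome 15, 7090614 to 7197489), fell from 11.7 ± 0.938 to 4.03 ± 0.423 FPKM (SD, n = 3 per group), a log2 fold change of -1.34 (SE 0.08). Stat3, the transcription factor activated by the receptor, fell from 23.2 ± 1.23 to 8.02 ± 0.346 FPKM (log2 fold change -1.43, SE 0.05). Il6st, the shared subunit gp130, fell less, from 12.8 ± 0.535 to 9.97 ± 0.544 FPKM (log2 fold change -0.33, SE 0.06). Socs3, a feedback inhibitor and direct STAT3 target (chromosome 11, 117966079 to 117970047), fell from 72.3 ± 8.92 to 2.80 ± 0.160 FPKM, 25.8 times lower, with a log2 fold change of -4.26 (SE 0.09), the lowest on the log2(FPKM + 1) scale of the genes that met the naming rule. By the plain ratio of FPKM means Pou2f3 fell slightly more, 26.4 times (compared after the values were seen). The limma adjusted p values of these genes were 2.01e-06 for Lifr, 1.97e-07 for Stat3, 7.62e-04 for Il6st and 1.46e-08 for Socs3.

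Of the 29 tested members of the LIF receptor and STAT3 list, 20 fell, 5 rose and 4 did not pass, with 20 and 5 when adjusted over the list alone. By camera the list was lower than other genes (adjusted p = 0.00437), and not past the threshold at adjusted p = 0.160 with an estimated correlation. Ier3, an early response gene, fell from 83.8 ± 2.65 to 17.3 ± 1.95 FPKM, and Ccnd3, a D-type cyclin, from 144 ± 4.30 to 70.7 ± 0.0842 FPKM. Myc, named after its values were seen, fell from 12.4 ± 3.96 to 1.44 ± 0.319 FPKM, and Egr1, also named afterwards, rose from 3.13 ± 1.41 to 7.54 ± 0.428 FPKM.

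**Figure D1:**
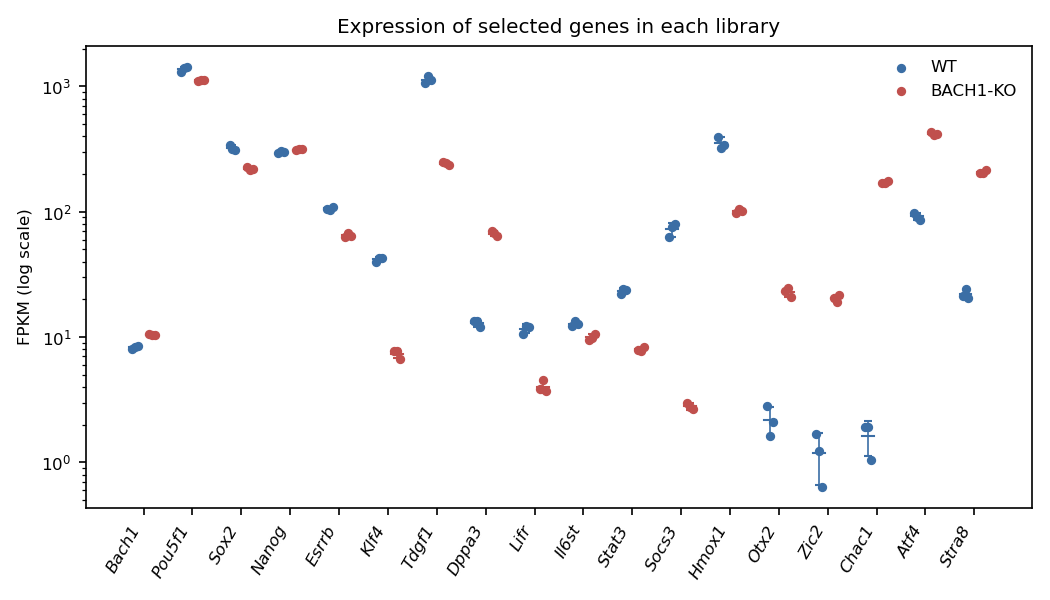
FPKM on a log scale of 18 genes in each library, WT in blue and BACH1-KO in red; points are libraries, horizontal lines are means and bars are SD over 3 libraries. Socs3 lies at 62.3 to 79.5 FPKM in WT and 2.68 to 2.98 FPKM in knockout, while Nanog lies at 295 to 302 FPKM in WT and 309 to 316 FPKM in knockout.

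Core pluripotency factors stayed abundant in the knockout cells, while several naive-state genes fell several-fold. Pou5f1, which encodes OCT4, went from 1377 ± 62.0 to 1115 ± 11.0 FPKM (log2 fold change -0.30, adjusted p = 1.16e-04) and Sox2 from 324 ± 15.4 to 221 ± 5.38 FPKM (log2 fold change -0.55, adjusted p = 5.16e-06). Nanog was at 298 ± 3.96 and 313 ± 3.68 FPKM (log2 fold change 0.07, adjusted p = 0.0419). Klf4, a naive-state factor downstream of STAT3, fell from 41.7 ± 2.03 to 7.39 ± 0.607 FPKM, and Esrrb, an orphan receptor of the naive network, from 106 ± 2.51 to 64.9 ± 2.38 FPKM. Nanog lies on chromosome 6, whose genes were higher as a set in knockout, and its call was lost without any 1 of the 6 libraries (log2 fold change 0.06 to 0.08) and with a constant prior variance (adjusted p = 0.129). Over all its alternatives the log2 fold change of Nanog ran from 0.06 to 0.24, the highest under quantile normalization. Pou5f1 was not called after quantile normalization (log2 fold change -0.04, adjusted p = 0.316, with the log2 fold change ranging from -0.34 to -0.04 over its alternatives).

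In the naive pluripotency list, 18 of 23 tested members fell and 5 rose, also when adjusted over the list alone. Camera placed the list below other genes (adjusted p = 0.00271); the test gave adjusted p = 0.162 with an estimated correlation. Tdh, the threonine dehydrogenase typical of mouse embryonic stem cells, fell from 445 ± 11.9 to 97.3 ± 0.811 FPKM, and Tcl1, an AKT co-activator, from 154 ± 0.555 to 47.9 ± 0.332 FPKM. Dppa3, a maternal-effect gene that lies on chromosome 6, rose from 13.0 ± 0.898 to 66.9 ± 3.33 FPKM. All 19 tested members of the general pluripotency list passed, 14 lower and 5 higher, with the same counts when adjusted over the list alone. Tdgf1, a NODAL co-receptor, fell from 1130 ± 72.0 to 242 ± 6.82 FPKM and Fgf4 from 128 ± 9.22 to 62.4 ± 1.13 FPKM. Dnmt3l, a cofactor of de novo DNA methylation, fell from 227 ± 5.14 to 161 ± 1.76 FPKM, and Fbxo15, an OCT4 target, rose from 85.5 ± 2.67 to 206 ± 2.15 FPKM. As a set this list did not pass by camera (adjusted p = 0.0794). It passed with no filter on low values (adjusted p = 0.01003) and without chromosome 6 (adjusted p = 0.0299), and its values ranged from 3.12e-05 to 0.395 over the alternatives.

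Of 24 tested formative and primed pluripotency genes 16 rose, 7 fell and 1 did not pass, with 16 and 7 when adjusted over the list alone. The list did not pass by camera (adjusted p = 0.0549), and 7 of its 15 alternatives left it there, with values from 0.00223 to 0.588 over all of them. It passed with no filter on low values (adjusted p = 0.0450), under quantile normalization (0.0418), without the hepatocyte list (0.0476) and by fry (0.00223). It also passed without the first (adjusted p = 0.0295), second (0.0377) or last WT column (0.0422) and without the last knockout column (0.0464). Otx2, a transcription factor of the formative state, rose from 2.19 ± 0.599 to 22.8 ± 1.96 FPKM. Sox3 rose from 1.34 ± 0.101 to 5.51 ± 0.222 FPKM and Cldn6, a tight junction gene, from 35.4 ± 0.421 to 74.1 ± 1.71 FPKM. Zic2, named after its values were seen, rose from 1.18 ± 0.526 to 20.5 ± 1.21 FPKM. The members that fell include Etv4, from 48.4 ± 3.46 to 3.47 ± 0.334 FPKM, and Spry4, from 36.8 ± 9.86 to 3.59 ± 0.189 FPKM, both known targets of FGF and ERK signalling.

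Of 22 tested germline genes 18 rose, 3 fell and 1 did not pass, with 18 and 3 when adjusted over the list alone. Camera gave adjusted p = 2.54e-04 with the direction higher, and adjusted p = 0.127 with an estimated correlation. Stra8, the retinoic acid target that marks meiotic entry, rose from 22.1 ± 1.98 to 207 ± 5.31 FPKM, and Sycp3, a synaptonemal complex component, from 7.75 ± 0.607 to 96.3 ± 1.91 FPKM. Taf7l, a germ cell TFIID subunit, rose from 1.28 ± 0.148 to 14.4 ± 0.986 FPKM, and Mael, a piRNA pathway gene, from 6.53 ± 0.206 to 18.7 ± 0.940 FPKM. Stra8 lies on chromosome 6. In the list of the 2-cell-like state, a rare state with transcripts of the early embryo, 9 of 13 tested members rose, 1 fell and 3 did not pass, with 9 and 1 when adjusted over the list alone. The set test gave adjusted p = 0.0106, and adjusted p = 0.162 with an estimated correlation. Usp17le rose from 0.744 ± 0.0535 to 4.17 ± 0.371 FPKM, Gm8300 from 2.95 ± 0.268 to 10.1 ± 0.987 FPKM, Arg2 from 0.744 ± 0.193 to 4.90 ± 0.791 FPKM and Ddit4l from 2.76 ± 0.115 to 6.38 ± 0.114 FPKM. Usp17le and Gm8300 belong to multicopy families, whose near-identical copies can share reads. Several of these genes are low in WT, and low genes as a whole were higher in knockout: the 5182 genes with a mean under 0.5 FPKM over all 6 libraries had library medians of 0.0217 to 0.0253 FPKM in WT and 0.0978 to 0.0990 FPKM in knockout.

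Germ layer and extraembryonic lists did not pass by camera, and their members moved both ways or were little expressed. Of the mesendoderm and mesoderm list only 7 of 29 genes were expressed enough to test, and 0 rose, 3 fell and 4 did not pass (0 and 3 when adjusted over the list alone, set adjusted p = 0.471). Bmp4, a BMP ligand, fell from 37.5 ± 5.22 to 9.25 ± 0.822 FPKM, Cdx1 from 4.05 ± 0.248 to 1.45 ± 0.406 FPKM and Eomes from 3.15 ± 0.400 to 2.24 ± 0.0151 FPKM. In the neuroectoderm list 3 of 12 tested members rose, 5 fell and 4 did not pass, equally when adjusted over the list alone. Pax6, an eye and brain regulator, rose from 0.571 ± 0.244 to 7.40 ± 0.351 FPKM and Tubb3, a neuronal tubulin, from 32.1 ± 1.06 to 65.2 ± 0.971 FPKM. Gap43, a growth cone gene, fell from 23.7 ± 2.81 to 8.60 ± 1.32 FPKM and Elavl3 from 3.47 ± 0.109 to 1.65 ± 0.0937 FPKM. The mean log2 fold change of this list was 0.003, the median -0.04 and the direction of the test was lower (adjusted p = 0.754). The trophoblast list had 6 higher, 6 lower and 1 not past of 13, also when adjusted over the list alone (set adjusted p = 0.958). Tfap2c rose from 12.6 ± 1.17 to 29.6 ± 0.700 FPKM and Fgfr2 from 0.563 ± 0.122 to 3.52 ± 0.157 FPKM, while Krt19 fell from 44.7 ± 5.20 to 10.9 ± 0.643 FPKM and Id2 from 34.2 ± 2.49 to 2.68 ± 0.584 FPKM. Markers of fibroblast feeder cells, which some embryonic stem cell cultures use, had 3 higher and 6 lower of 9 tested, also when adjusted over the list alone (set adjusted p = 0.116). Vim fell from 186 ± 9.31 to 54.9 ± 1.35 FPKM, Thy1 from 18.8 ± 0.550 to 10.2 ± 0.190 FPKM, Pdgfrb from 3.78 ± 0.195 to 1.31 ± 0.187 FPKM and Timp2 from 3.62 ± 0.0986 to 1.55 ± 0.205 FPKM. The feeder list passed without 1 knockout library, the second column (adjusted p = 0.0449, with 6.97e-06 to 0.914 over all alternatives).

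The primitive and definitive endoderm list had 6 higher, 7 lower and 4 not past of 17 tested members, with 6 and 7 when adjusted over the list alone. Its largest rises were Apoa1, from 0.947 ± 0.504 to 83.8 ± 0.802 FPKM, and Ttr, from 0.110 ± 0.139 to 36.9 ± 2.51 FPKM. Both are also hepatocyte transcripts and rose with the hepatocyte list. Rbp4, a retinol carrier also abundant in liver, rose from 9.21 ± 0.296 to 25.7 ± 1.85 FPKM, and Sparc, a matrix protein of parietal endoderm, fell from 92.5 ± 3.46 to 48.9 ± 1.32 FPKM. The mean log2 fold change was 0.39, the median -0.004, and camera's direction was lower (adjusted p = 0.991).

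Of 29 tested BACH1 and NRF2 target genes 19 fell, 5 rose and 5 did not pass, with 19 and 5 when adjusted over the list alone. The set test gave adjusted p = 0.0109 with the direction lower, and adjusted p = 0.244 with an estimated correlation. It was also not past the threshold after quantile normalization (adjusted p = 0.0768, with 1.52e-05 to 0.244 over the alternatives). Hmox1, heme oxygenase and the best known gene repressed by BACH1, fell from 353 ± 38.6 to 102 ± 3.45 FPKM (log2 fold change -1.78, SE 0.07, adjusted p = 2.34e-07). This fall is opposite to the rise that the loss of a repressor would give, and its cause was not tested. Me1, a malic enzyme, fell from 25.2 ± 0.630 to 9.73 ± 0.489 FPKM and Cbr3, a carbonyl reductase, from 23.2 ± 1.28 to 4.95 ± 0.752 FPKM. Herpud1, an endoplasmic reticulum stress gene that is also on the ATF4 list, rose from 9.70 ± 1.32 to 72.3 ± 2.29 FPKM. The other members that rose were Srxn1, Slc40a1, Sqstm1 and Abcb6, named after their values were seen. In the heme and iron list 14 of 27 tested members fell, 6 rose and 7 did not pass, also when adjusted over the list alone (set adjusted p = 0.143). Blvra, biliverdin reductase, fell from 20.7 ± 0.698 to 8.53 ± 0.351 FPKM and Ireb2, an iron-responsive element binding protein, from 67.0 ± 0.861 to 40.7 ± 0.589 FPKM, while Uros, an enzyme of heme synthesis, rose from 2.80 ± 0.323 to 13.1 ± 1.201 FPKM. This list passed with no filter on low values (adjusted p = 0.0189, with 2.08e-06 to 0.275 over the alternatives).

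Of 29 tested genes of the ATF4 and unfolded protein response list 21 rose and 8 fell, also when adjusted over the list alone. Camera gave adjusted p = 4.34e-04 with the direction higher, and adjusted p = 0.127 with an estimated correlation. Chac1, a glutathione-degrading enzyme induced by ATF4, rose from 1.64 ± 0.507 to 171 ± 4.54 FPKM (log2 fold change 6.05, SE 0.13, adjusted p = 1.59e-08), a ratio of 104. Atf4 itself rose from 91.7 ± 5.88 to 419 ± 11.7 FPKM, Trib3, a pseudokinase, from 7.70 ± 0.254 to 46.1 ± 0.271 FPKM, and Pck2, the mitochondrial PEP carboxykinase, from 4.80 ± 0.484 to 45.0 ± 0.780 FPKM. The 8 members that fell are chaperones and folding factors of the endoplasmic reticulum (Hsp90b1, Sdf2l1, Hyou1, Hspa5, Pdia4, Manf, Calr and Creld2, named after their values were seen). Hsp90b1 fell from 367 ± 9.53 to 239 ± 6.49 FPKM and Hspa5, which encodes BiP, from 203 ± 18.8 to 169 ± 2.07 FPKM. Other members with a known role in the endoplasmic reticulum rose, among them Herpud1, the co-chaperone gene Dnajb9, from 11.4 ± 1.34 to 20.6 ± 1.00 FPKM, and Xbp1, from 39.2 ± 5.28 to 68.8 ± 3.17 FPKM (Dnajb9 and Xbp1 also named afterwards). Among p53 targets 18 of 25 tested members rose, 5 fell and 2 did not pass, with 18 and 6 when adjusted over the list alone. The set test gave adjusted p = 0.00869, and adjusted p = 0.244 with an estimated correlation. Ccng1, cyclin G1, rose from 94.8 ± 2.19 to 263 ± 3.60 FPKM, Sesn2, a sestrin also on the ATF4 list, from 11.6 ± 0.582 to 40.6 ± 2.02 FPKM, Plk3 from 7.26 ± 0.586 to 26.5 ± 0.139 FPKM and Plk2 from 9.43 ± 0.290 to 21.7 ± 0.712 FPKM.

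Of 24 tested cholesterol synthesis genes 21 fell, 2 rose and 1 did not pass, with 21 and 2 when adjusted over the list alone. The median log2 fold change was -0.91, and camera gave adjusted p = 1.94e-05, the smallest of the 25 lists, and adjusted p = 0.127 with an estimated correlation. Fdft1, squalene synthase, fell from 99.2 ± 2.52 to 31.5 ± 0.445 FPKM, Hmgcs1, HMG-CoA synthase, from 131 ± 3.67 to 52.1 ± 2.20 FPKM, Fdps from 281 ± 3.68 to 116 ± 5.19 FPKM and Nsdhl from 40.6 ± 1.32 to 15.6 ± 0.115 FPKM.

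In glycolysis 19 of 22 tested members fell, 2 rose and 1 did not pass, also when adjusted over the list alone. The set test gave adjusted p = 2.54e-04, and adjusted p = 0.296 with an estimated correlation. Slc2a1, the glucose transporter GLUT1, fell from 571 ± 12.5 to 277 ± 4.40 FPKM, Aldoc, an aldolase, from 82.5 ± 4.97 to 24.7 ± 0.698 FPKM and Pfkp from 129 ± 6.34 to 57.9 ± 0.566 FPKM. In the hypoxia list 18 of 23 fell, 3 rose and 2 did not pass, also when adjusted over the list alone. Camera gave adjusted p = 0.00101, and adjusted p = 0.339 with an estimated correlation. Egln3, an oxygen-sensing prolyl hydroxylase, fell from 71.1 ± 0.993 to 13.0 ± 0.442 FPKM, Ldha from 2783 ± 190 to 1156 ± 28.0 FPKM and Pdk1 from 93.3 ± 0.881 to 45.4 ± 1.01 FPKM. Slc2a1, Ldha and Pdk1 are on both lists. In oxidative phosphorylation 28 of 35 fell, 3 rose and 4 did not pass, also when adjusted over the list alone, with small changes (median log2 fold change -0.30). The set test gave adjusted p = 4.65e-04, adjusted p = 0.247 with an estimated correlation and adjusted p = 0.139 after quantile normalization (2.14e-06 to 0.247 over the alternatives). Atp5c1, an ATP synthase subunit, fell from 978 ± 19.9 to 465 ± 10.8 FPKM, Cox6b1 from 714 ± 8.56 to 425 ± 9.55 FPKM, Uqcrfs1 from 237 ± 11.0 to 147 ± 1.00 FPKM and Atp5o from 649 ± 6.92 to 462 ± 3.34 FPKM.

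Of 34 tested cell cycle genes 22 fell, 8 rose and 4 did not pass, with 23 and 8 when adjusted over the list alone. The set test gave adjusted p = 0.0169, adjusted p = 0.339 with an estimated correlation and adjusted p = 0.328 after quantile normalization (3.50e-05 to 0.339 over the alternatives). Mki67, the proliferation marker Ki-67, fell from 23.7 ± 0.861 to 8.67 ± 0.219 FPKM, Bub1b, a spindle checkpoint kinase, from 104 ± 0.836 to 61.4 ± 0.703 FPKM and Mcm4, a replicative helicase subunit, from 119 ± 3.51 to 77.2 ± 0.845 FPKM.

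The remaining lists did not pass by camera. Imprinted genes had 12 higher, 6 lower and 4 not past of 22, also when adjusted over the list alone (set adjusted p = 0.280, and 0.0389 with a filter at 5 FPKM, among 3.32e-05 to 0.971 over the alternatives). Grb10, a growth-restricting adaptor, rose from 2.31 ± 0.182 to 20.2 ± 0.865 FPKM, Ndn, necdin, from 7.13 ± 0.378 to 17.7 ± 0.366 FPKM and Impact from 50.7 ± 1.08 to 85.7 ± 1.30 FPKM, while Plagl1 fell from 4.75 ± 0.234 to 1.43 ± 0.0846 FPKM. Interferon response genes had 7 higher, 5 lower and 5 not past of 17, also when adjusted over the list alone (set adjusted p = 0.754). Bst2, tetherin, fell from 161 ± 11.5 to 78.9 ± 1.54 FPKM and Ifitm3 from 275 ± 8.23 to 149 ± 8.15 FPKM, while Tap1 rose from 2.58 ± 0.0910 to 5.81 ± 0.229 FPKM and Ifi27 from 0.295 ± 0.0825 to 2.37 ± 0.171 FPKM. Cytosolic ribosomal protein genes had 18 higher, 12 lower and 11 not past of 41, also when adjusted over the list alone (set adjusted p = 0.471). Rpl32, on chromosome 6, rose from 5035 ± 214 to 7123 ± 183 FPKM, Rps27a from 3541 ± 255 to 5747 ± 447 FPKM and Rpl35 from 2854 ± 69.8 to 3516 ± 16.5 FPKM, while Rpl15 fell from 606 ± 7.86 to 495 ± 9.39 FPKM. Ribosomal protein genes have many processed pseudogenes that can share their reads. Immediate early and stress genes had 8 higher, 8 lower and 2 not past of 18, also when adjusted over the list alone (set adjusted p = 0.958). Atf3 rose from 0.543 ± 0.102 to 14.5 ± 0.956 FPKM and Jun from 1.24 ± 0.0471 to 7.31 ± 0.362 FPKM, while Hspb1, a small heat shock protein, fell from 1128 ± 23.3 to 506 ± 2.09 FPKM. Histone genes had 5 higher, 6 lower and 9 not past of 20, also when adjusted over the list alone (set adjusted p = 0.996). Their mean log2 fold change was -0.08 and median -0.18 while the direction of the test was higher, and it turned to lower under quantile and median-of-ratios scaling. Hist3h2a rose from 6.85 ± 0.831 to 50.9 ± 5.54 FPKM and H2afx from 214 ± 9.41 to 308 ± 2.37 FPKM, while Hist2h3b fell from 3.31 ± 0.749 to 0.455 ± 0.167 FPKM. H2afz was at 1368 ± 26.2 and 1137 ± 22.0 FPKM, lower as deposited, with a log2 fold change of -0.27 (adjusted p = 7.03e-05) that turned to 0.004 (adjusted p = 0.897) under quantile normalization, ranging from -0.28 to 0.004.

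**Figure D2:**
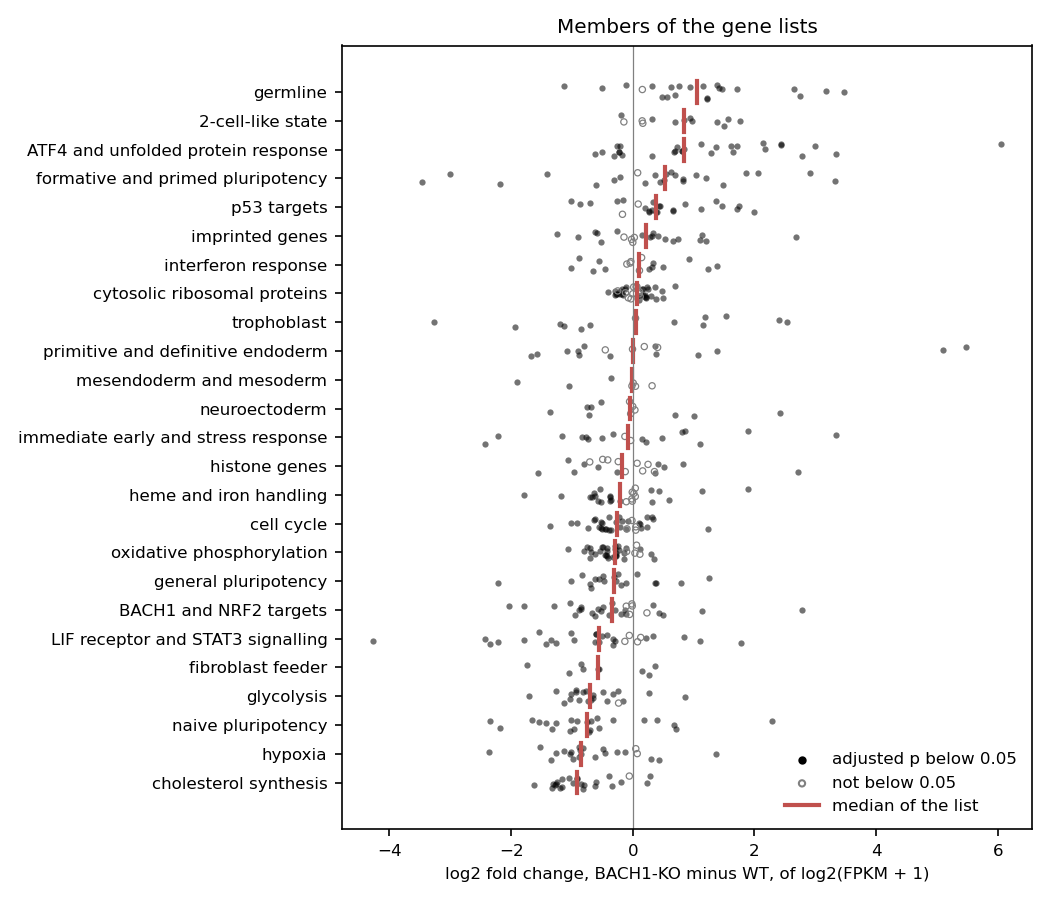
Log2 fold change (BACH1-KO minus WT, of log2(FPKM + 1)) of each tested member of the 25 lists; filled points passed the threshold, open points did not, and red bars are list medians. Lists are ordered by median, from cholesterol synthesis at -0.91 to the germline at 1.05.

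Across the 25 lists, 12 passed by camera with the preset correlation. None passed with an estimated correlation (0 of 25, smallest adjusted p = 0.127), and 19 passed by fry, which does not compare a list with other genes. Fry's test for change in either direction passed for all 25.

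Among genes that met the naming rule, the lowest log2 fold change after that of Socs3 was that of Id1. This gene, an inhibitor of DNA binding induced by BMP signals, fell from 157 ± 4.16 to 8.33 ± 1.59 FPKM (log2 fold change -4.09, SE 0.10, adjusted p = 3.08e-08), 18.8 times lower. S100a6, a calcium-binding protein, fell from 130 ± 3.50 to 9.01 ± 1.22 FPKM and Pcolce, a procollagen processing enhancer, from 76.4 ± 3.05 to 7.30 ± 0.890 FPKM. The keratins Krt42 and Krt17 fell from 49.1 ± 1.43 to 3.51 ± 0.569 and from 24.5 ± 5.46 to 2.78 ± 0.341 FPKM. Pou2f3 fell from 15.5 ± 1.43 to 0.588 ± 0.0374, Hopx, an atypical homeodomain gene, from 34.9 ± 3.43 to 2.65 ± 0.707, and Tesc, tescalcin, from 16.3 ± 0.454 to 0.874 ± 0.184 FPKM. These log2 fold changes ran from -3.71 for S100a6 to -2.74 for Krt17, and all 3 knockout libraries lay below all 3 WT libraries for each gene. In all, 12 genes fell by a log2 of 3 or more and 59 rose by as much.

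Of the 12 largest rises, 11 were transcripts that hepatocytes make in bulk, and Chac1 was the other. Alb, serum albumin, was at 0.0738, 0.701 and 1.39 FPKM in the WT libraries and at 461, 471 and 471 FPKM in the knockout libraries (log2 fold change 8.16, SE 0.24, adjusted p = 6.10e-08). Serpina1e, an alpha-1-antitrypsin gene, was listed at 0 in all 3 WT libraries and was at 59.2, 65.2 and 63.7 FPKM in the knockout libraries. Serpina3k rose from 0.103 ± 0.0927 to 96.2 ± 2.68 FPKM, the plasma glycoprotein gene Ahsg from 0.688 ± 0.301 to 67.1 ± 2.12, Serpina1b from 0.0715 ± 0.0830 to 32.5 ± 1.78 and Cyp2e1 from 0.252 ± 0.369 to 35.6 ± 1.77 FPKM. Apoa2, Fabp1 and the urinary protein gene Mup3 were at 0.604 ± 0.788, 0.804 ± 1.12 and 1.02 ± 1.68 FPKM in WT, and at 47.5 ± 3.63, 63.0 ± 5.60 and 59.5 ± 1.03 FPKM in knockout. Members of the Serpina1 and Mup families are close copies whose reads can be split between them, and Fabp1 lies on chromosome 6. A hepatocyte list was assembled after these values were seen, in part from genes seen to be high in knockout. In that list 90 of 91 genes were higher in every knockout library than in every WT library, a count that describes the list and tests nothing. Fah, expressed in both genotypes, was the exception at 42.5 ± 2.78 and 29.3 ± 1.16 FPKM. The median of the list was 0.0247 FPKM in WT and 6.97 FPKM in knockout, and 3 members reached a mean of 1 FPKM in WT (2 to 6 with any 1 WT library left out), among them Mup3, at 0, 0.0973 and 2.96 FPKM in the WT libraries. Afp, the fetal albumin-like gene, was listed at 0 in all 3 knockout libraries and had a mean of 0.0217 FPKM in WT.

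**Figure D3:**
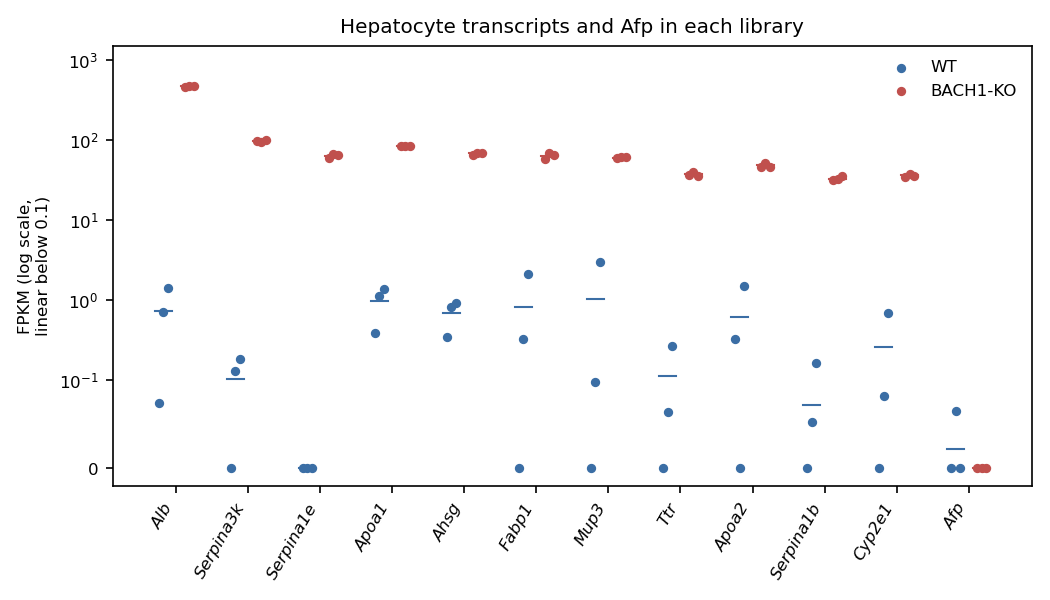
FPKM of 11 hepatocyte transcripts and Afp in each library, on an axis that is logarithmic above 0.1 FPKM and linear below; points are libraries and horizontal lines are means over 3 libraries (WT blue, BACH1-KO red). Alb lies at 461 to 471 FPKM in knockout and at most 1.39 FPKM in WT, and Afp is at 0 in knockout.

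Outside the hepatocyte list, and named after their values were seen, further large rises included those of Nupr1, Sepp1, Krcc1, Rhob and Mgst1. Nupr1, a stress-induced chromatin protein, went from 17.0 ± 0.887 to 317 ± 13.2 FPKM (log2 fold change 4.15, SE 0.05, adjusted p = 1.78e-09). Sepp1 went from 3.40 ± 0.206 to 55.9 ± 3.16 FPKM, and Rhob, a small GTPase, from 5.43 ± 0.615 to 61.3 ± 2.95 FPKM. Mgst1, a glutathione transferase, rose from 5.31 ± 0.319 to 55.6 ± 1.75 FPKM and Krcc1 from 2.77 ± 0.541 to 42.7 ± 3.46 FPKM, and both lie on chromosome 6. Vtn, Uox and Azgp1, which are abundant in liver though not on the list, rose from under 1 FPKM to 11.3 ± 0.842, 8.60 ± 0.340 and 7.71 ± 0.556 FPKM. The list is not a full catalogue of liver transcripts, so a gene outside it can still belong to the same pattern.

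Chromosome 6 stood apart from the other autosomes. Its 537 tested genes outside the hepatocyte list had a median log2 fold change of 0.31 and 72.3% were higher in knockout, against a median of -0.04 and 47.1% for the other autosomes. The difference of medians was 0.35 (95% bootstrap interval over genes 0.28 to 0.40). It was 0.34 in each knockout library, taken against the WT mean of each gene. Against the same median of all autosomes but 6, next came chromosome 12, at 0.12 above it with its own genes included, and chromosome X at 0.11. Of the chromosome 6 genes 317 rose and 95 fell. The genes Nanog, Dppa3, Stra8, Rpl32, Fabp1, Krcc1 and Mgst1 described above lie on it.

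**Figure D4:**
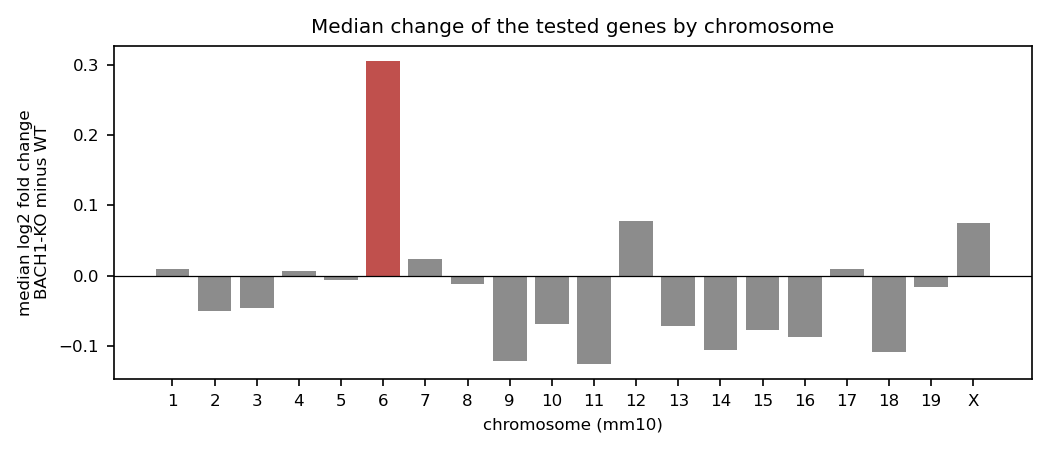
Median log2 fold change (BACH1-KO minus WT, of log2(FPKM + 1)) of the tested genes of each autosome and of X, without the hepatocyte list; bars start at 0. Chromosome 6, in red, has a median of 0.31 over 537 genes, and the medians of the other autosomes and X lie between -0.13 and 0.08. Chromosome Y, with 4 tested genes and a median of -0.94, is not drawn.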

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

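The tests without the hepatocyte list, without chromosome 6 and against a fold change of 1.5 were chosen after the data were seen. Leaving out each library in turn gave 8714 to 9404 genes past the threshold, and quantile normalization gave 9260, of which 8432 were among the 9378; 121 of the 9378 had the opposite sign there, and 0 in the other settings. More of the called genes were higher than lower with no filter (6580 and 5075) and with median-of-ratios scaling (50.5% of 9355 higher), unlike in the main fit. No scaling or filter moved the median log2 fold change by over 0.1. With a filter at 5 FPKM, which tests fewer genes, 2942 genes were higher and 817 doubled or halved. Against a fold change of 1.5, which asks for larger changes, 2319 passed, 1325 higher and 994 lower, and Bach1 (log2 fold change 0.3017) did not; its log2 fold change ran from 0.25 to 0.33 over all alternatives. Of 1842 alternatives for 133 named genes, 1816 kept direction and side of the threshold, 25 lost the call, 17 of these against a fold change of 1.5, and H2afz turned to 0.004115 under quantile normalization. For the lists, 324 of 372 alternatives kept direction and side. The camera test with an estimated correlation ended all 12 list calls and gave the highest p of any alternative for each. Its adjusted p was 0.1619 for naive pluripotency, 0.1597 for LIF receptor and STAT3 signalling and 0.2439 for BACH1 and NRF2 targets. The last of these lists also lost its call under quantile normalization (0.07679). The estimated correlation was below the preset 0.01 for the germline (-0.0012), 2-cell-like (-0.036), LIF receptor and STAT3 (0.0030) and ATF4 (0.0081) lists. For these a larger correlation did not end the call. For the other lists that had passed the estimate was above the preset value, though for cholesterol synthesis only slightly (0.0198). The camera adjusted p of that list still went from 1.94e-05 to 0.127, the same value as for the germline list. A larger correlation is therefore not shown to have ended those calls either. General pluripotency passed with no filter (0.01003), without chromosome 6 (0.02987) and by fry (3.118e-05), and mesendoderm by fry (0.000258). Formative and primed pluripotency passed in 8 of 15 alternatives, with adjusted p from 0.002228 by fry to 0.5878 with an estimated correlation. Lists that did not pass changed direction as follows. Endoderm turned at 5 FPKM (0.4352), without chromosome 6 (0.9723), by fry (0.2263) and without the last WT or last knockout column (0.9201 to 0.9837 over the fits that left out a library). Histone genes turned with no filter (0.735), under quantile (0.9483) and median-of-ratios scaling (0.944) and without the first WT or first knockout column (0.7914 to 0.9837 over those fits). Imprinted genes turned with no filter (0.9706) and trophoblast at 5 FPKM (0.63) and by fry (0.8892). Neuroectoderm (0.1746) and immediate early genes (0.01991) turned by fry. Apart from the 5 FPKM filter and the larger fold change asked for, the cause was not tested. No paired analysis was possible because the columns cannot be tied to sample titles, so the planned block on the ending of the title was not run. No symbol occurs in more than 1 row, so summing such rows changed nothing. Absolute depth is unknown, which limits what can be said of genes listed at 0.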

Other observations

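Tests chosen only after the result was seen were those of hepatic differentiation, of liver RNA on chromosome 6, of sequencing depth and of the receptor genes. The ERK, BMP and Y-linked gene lists were also written after the data were seen, and their counts are descriptions.

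Feedback targets of ERK signalling, which restrain or report that pathway, were mostly lower in knockout. Of 17 tested genes 13 fell, 2 rose and the rest did not pass. Beside Etv4 and Spry4, the phosphatase gene Dusp6 fell from 26.1 ± 2.40 to 9.15 ± 0.291 FPKM and Spred1 from 15.0 ± 1.19 to 7.47 ± 0.423 FPKM. The 2 that rose were Dusp4, from 3.87 ± 0.344 to 6.62 ± 0.479 FPKM, and Egr1.

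Targets of BMP and SMAD signalling moved one way among those past the threshold. Of 10 tested genes 8 fell and 0 rose by limma. Beside Id1 and Id2, Id3 fell from 25.7 ± 6.78 to 10.6 ± 0.0281 FPKM, the inhibitory SMAD gene Smad7 from 8.66 ± 1.96 to 2.36 ± 0.114 FPKM and Bambi, a decoy receptor, from 3.88 ± 0.343 to 2.19 ± 0.102 FPKM. Smad6 was at 2.86 ± 0.411 and 2.66 ± 0.0545 FPKM (adjusted p = 0.508).

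The number of genes past the threshold in the real grouping was 9378. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and 1 of the 10, the real one, gave as many. The highest of the other splits gave 0 genes by limma, with at most 47 at an unadjusted p under 0.05 against 9555 for the real one. Each of those splits mixes the genotypes on both sides, so the difference between genotypes enters its residual spread and lowers its count. Their low counts therefore do not show how many genes would pass by chance.

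Hepatocyte transcripts were found at like levels in all 3 knockout libraries, led by Alb at 468 ± 5.91, Serpina3k at 96.2 ± 2.68 and Apoa1 at 83.8 ± 0.802 FPKM, and 3 of the 91 genes had a mean of at least 1 FPKM in WT (2 to 6 with any 1 WT library left out). Hepatic differentiation of the knockout cells would need hepatoblast and early endoderm genes to rise as well, by a median log2 ratio of at least 1, and that median was -0.0868 (95% bootstrap interval -0.26 to 0.54) over 23 genes, with Afp listed at 0 in knockout. In a list of other liver cell types, whose values had not been seen, 20 of 27 genes separated the groups as higher and 2 as lower, Ptgs1 and Fcgr2b, which were 2 of the 3 tested by limma, and the median log2 ratio lay above 99.98% of 10000 random lists matched on WT level (C1qa and Cd5l, macrophage genes listed at 0 in WT, were at 0.983 ± 0.279 and 0.841 ± 0.245 FPKM in knockout). The median log2 ratio was 1.84 for this list and 0.78 for the random lists, so genes equally low in WT also rose, though less. RNA or reads from adult liver in the knockout libraries are therefore a candidate explanation, and the sorting of clones, which came before the culture, would not remove them. Some other effect of the genotype on liver genes was not tested and stays open.

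Chromosome 6 genes were higher in knockout by a median of 0.35 over the other autosomes. A bias by GC content or transcript length is argued against, since the shift was 0.33 (95% bootstrap interval 0.29 to 0.39) once both trends were removed, and so is liver RNA, since it was 0.33 (0.25 to 0.41) over 342 genes without the hepatocyte list and genes under 5 FPKM in WT. Across 5 consecutive segments with about equal numbers of genes the lowest median shift was 0.22, between 82725025 and 97233315, so all 5 segments were shifted. Smaller parts of the chromosome were not examined. An extra copy of chromosome 6 in the knockout cells, or in part of them, is a candidate explanation, and 3 copies over 2 in every cell would give a log2 ratio of 0.58 without compensation. A response of chromosome 6 genes to the loss of BACH1 stays open, as untested.

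Y-linked Ddx3y, Eif2s3y and Uty fell by 1.60, 1.10 and 0.76 on the log2 scale, the 3 tested of 7 Y-linked genes looked at.

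Genes at 0 in WT were detected in knockout more often than the reverse: 587 genes were listed at 0 in all WT libraries and above 0 in all knockout libraries, and 21 the other way round. The rise does not rest on choosing genes low in WT, since the 4883 genes under 0.5 FPKM in knockout had library medians of 0.0195 to 0.0241 FPKM in WT and 0.0848 to 0.0869 FPKM in knockout. By the depth estimate the shallowest knockout library was at a relative depth of 1.01. It had 1117 fewer genes at 0 than the WT library with the fewest, at a relative depth of 1.10. The range within WT was 112. This argues against a small difference in sequencing depth as the cause. The estimate searched only a limited range around equal depth, so a larger difference stays open. Liver RNA is argued against as the whole cause, because 96 olfactory, vomeronasal and taste receptor genes, which liver does not use, had at least 2.46 times their WT mean in every knockout library. Genomic DNA in the knockout libraries cannot be told apart from wider transcription of silent genes: among genes under 0.5 FPKM in WT the median gain of multi-exon genes was 1.33 times that of single-exon genes, and its 95% bootstrap interval of 0.91 to 1.85 runs past the bounds of 0.67 to 1.5 that were set for an equal gain.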
